A study of Homo sapiens with 12 samples.

How the data were processed

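DLD-1 is a human colorectal adenocarcinoma cell line. The cells carried an auxin-inducible degron (AID), a tag that leads to proteasomal destruction of the tagged protein once auxin is added, either on RanBP3 (AID-RanBP3) or on RCC1 (RCC1-AID). RanBP3 is a cofactor of the nuclear export receptor XPO1, and RCC1 is the chromatin-bound exchange factor that loads the GTPase Ran with GTP. Per the labels, total RNA was extracted with a column kit and made into TruSeq total RNA libraries, and auxin was given at 1 mM for 4 h to AID-RanBP3 cells and for 6 h to RCC1-AID cells. The labels' protocol also mentions a 9 h treatment, which was not analysed here. Each of the 4 groups had 3 libraries, 12 in all. No auxin-treated cells without a degron tag and no protein measurements were analysed here. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

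The deposited values were whole-number read counts per gene, not normalized, for 58051 Ensembl gene IDs in each library. CASAVA 1.8.2, STAR 2.6.1, featureCounts 1.6.3 and the genome build GRCh38 are named in the submitters' processing notes, with no settings. The annotation release, the strand setting and the handling of reads that match several genes are not given in the sources used here. Without the strand setting, reads from the stretch where a gene and an antisense or other partner overlap cannot be told apart. Of the IDs, 56948 were found in a table of gene names, 41445 of them with a symbol other than an ID, and 57447 IDs were found in GENCODE release 29, which gave positions on GRCh38. Among IDs with a total of at least 1000 counts, 4 sets, 8 IDs in all, had identical counts in all 12 libraries, and their repeated values made up 2.437% of all counts. The mitochondrially encoded mRNAs had 0 counts in all libraries. Library totals ranged from 9326243 to 43620542 counts.

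Genes were kept with filterByExpr of edgeR 4.0.16 (minimum count 10), which left 19607 genes. No pair of libraries agreed within sampling noise (lowest chi-square per gene 4.52 within groups and 2.68 between groups). Libraries were scaled with TMM factors. A quasi-likelihood model (glmQLFit, glmQLFTest) with 4 groups and 8 residual degrees of freedom was fitted to all 12 libraries, and p-values were adjusted by Benjamini-Hochberg. Genes with an adjusted p under 0.05 are called higher or lower. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are CPM values, counts scaled to the TMM-adjusted library total, given as mean ± SD. Changes are log2 fold changes ± SE. The comparisons were auxin against untreated in each line, the untreated lines against each other, and the difference between the auxin responses. Treatment time and cell line differ between the auxin comparisons along with the degraded protein. Principal components were computed from log2 CPM with a prior count of 2. R 4.3.3, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15 were used.

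The groups, the tests, the gene lists and the rule for named genes were fixed before the data were examined. The rule takes RANBP3, RCC1, RAN, XPO1, CYP1A1, CYP1B1, TIPARP, AHRR, AXIN2, LGR5, SMAD7, CDKN1A, MYC, FOS and EGR1 whatever their value; some items that the rule takes are not reported here. It adds the 10 called genes with the largest rise and the 10 with the largest fall in each auxin comparison, and 5 in each direction in the other comparisons, given a symbol, a mean log2 CPM of at least 1 and no overlap between the replicates of the groups. It also takes up to 4 members of each gene list with the smallest p. Gene lists of signalling targets, stress responses, the cell cycle, ribosomes, nuclear transport, RNA classes and markers of other cell types were tested with camera at a preset correlation of 0.01 between genes and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 33 lists with at least 3 genes tested. List members were also counted with p adjusted over the list alone. Mean log2 CPM values of the lists were compared by exact enumeration of the 400 splits of the libraries within lines, two-sided, and the overlap of calls was tested by one-sided Fisher's exact test.

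Same-numbered AID-RanBP3 libraries deviated together from their group means, with correlations of 0.299, 0.325 and 0.608 across genes. Replicate numbers come from the labels, which do not say what they share. Alternatives covered other scaling, no filter and a filter of 50 mean counts, DESeq2, limma-voom, the 6 libraries of a comparison alone, the replicate number as a block, a 2-fold minimum and each library left out in turn. Thinning of every library to 9326243 counts, offsets for GC content and gene length, 1 ID of each set identical at any total above 0, the mean auxin effect of both lines, an exact test of the FOXO list within pairs and DESeq2 values of CYP1A1 without the cutoff for outlying counts were added after the data were seen.

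The pipeline was tested on counts simulated independently around a single mean per gene over all libraries, at the real depths, with 200 genes changed. Apart from the changed genes they held no line difference, and they held no structure shared between libraries. The shares below hold for such counts and may differ for the real ones. In the RanBP3 simulation, run on 19249 genes, 37.3% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 95.5% of those changed 4-fold were called. The corresponding shares were 44.8%, 67.2% and 97% over 19288 genes for the RCC1 comparison, and 46.3%, 61.2% and 98.5% over 19280 genes for the untreated lines. For the difference between responses they were 20.9%, 59.7% and 86.4% over 19253 genes. Of the unchanged genes, 6, 14, 9 and 5 were called in these simulations, in that order.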

Results

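RNA levels were measured by total RNA sequencing in DLD-1 colorectal cancer cells whose RanBP3 or RCC1 protein carried an auxin-inducible degron. Untreated AID-RanBP3 cells, AID-RanBP3 cells after 4 h of auxin, untreated RCC1-AID cells and RCC1-AID cells after 6 h of auxin were each sequenced in 3 libraries. The untreated AID-RanBP3 libraries held 13924405, 26924139 and 11462796 counts in genes, and the auxin-treated ones held 17400626, 9326243 and 12955864. The RCC1-AID libraries were deeper, with 35183848, 43620542 and 34364988 counts without auxin and 26364720, 37482139 and 34622719 with auxin.

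The lines lay apart on the first principal component. It held 56.9% of the variance of log2 CPM, with the AID-RanBP3 libraries between -53.8 and -23.6 and the RCC1-AID libraries between 31.5 and 48.6. The second held 10.6% and set replicate 3 of both AID-RanBP3 groups apart, at -23.9 and -36.1. Within the lines the first component followed depth, with Pearson's r = 0.83 (exact permutation p = 0.0472) in AID-RanBP3 and r = 0.825 (p = 0.0361) in RCC1-AID cells, n = 6 libraries each, both with an adjusted p of 0.0472 over these relations. Spearman's rho was 0.714 in each line (exact permutation p = 0.136, adjusted p = 0.136). Without the 2 libraries farthest from the median depth, r was 0.635 and 0.103, so the relation in RCC1-AID cells rested on those libraries.

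**Figure D1:**
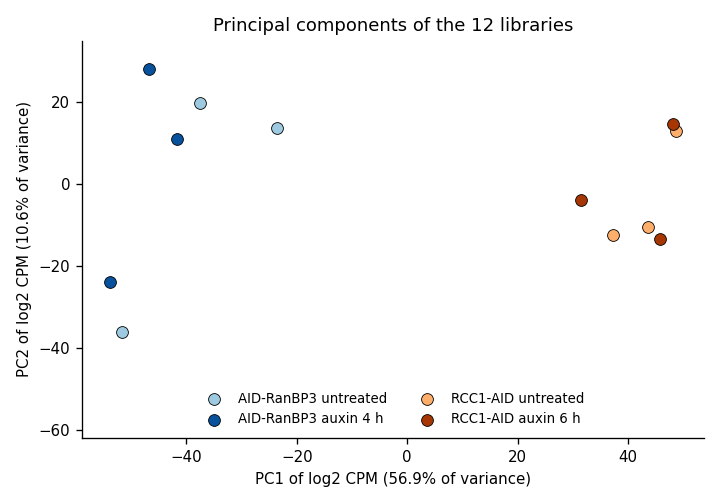
Principal components of log2 CPM in the 12 libraries, with the first component (56.9% of the variance) on the horizontal axis and the second (10.6%) on the vertical axis, in units of the component scores. Each point is 1 library, coloured by group; the AID-RanBP3 libraries lie left of the RCC1-AID libraries.

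The mRNAs of the tagged proteins come first. The degron acts on the protein, so their levels do not check which cells received auxin. In AID-RanBP3 cells RANBP3 (ENSG00000031823, chromosome 19, 5916139 to 5978142) stood at 48.1, 50.4 and 53.8 CPM without auxin and at 52.4, 50.9 and 54.8 CPM with auxin, a log2 fold change of 0.06 ± 0.08 (SE, n = 3 against 3, adjusted p = 0.962). RCC1 (ENSG00000180198, chromosome 1, 28505943 to 28539300) stood at 164 ± 1.28 CPM in untreated RCC1-AID cells and at 174 ± 17.3 CPM with auxin (log2 fold change 0.08 ± 0.08, adjusted p = 0.999). Protein loss was not measured here.

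Auxin treatment of AID-RanBP3 cells asked which transcripts change when this export cofactor is lost. After 4 h of auxin, AID-RanBP3 cells had higher levels of CYP1A1 (chromosome 15, 74719542 to 74725610), the cytochrome P450 that is the classical target of the aryl hydrocarbon receptor (AhR), at 277 ± 12.8 CPM against 23.6 ± 20.2 CPM in untreated cells (log2 fold change 3.47 ± 0.54, adjusted p = 0.0164, n = 3 per group as for every value here). CYP1B1 (chromosome 2, 38066973 to 38109902), another AhR target, rose from 35.3 ± 5.54 to 68.1 ± 2.42 CPM (0.94 ± 0.13, adjusted p = 0.00729). TXNIP (chromosome 1, 145992435 to 145996600), an arrestin-domain protein that binds thioredoxin and restrains glucose uptake, rose by 1.87 ± 0.30 (adjusted p = 0.0233, 86.5 ± 18.8 against 24.4 ± 9.15 CPM). The arrestin-domain genes ARRDC3 (chromosome 5, 91368724 to 91383359) and ARRDC4 rose by 1.65 ± 0.15 (adjusted p = 0.000178) and 1.28 ± 0.15 (adjusted p = 0.00125). The atypical cyclin CCNG2 (chromosome 4, 77157151 to 77433388) rose from 10.7 ± 2.6 to 32.2 ± 6.66 CPM (1.63 ± 0.20, adjusted p = 0.00163).

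Further risen genes were ADGRF1, an adhesion G protein-coupled receptor (1.40 ± 0.20, adjusted p = 0.0104), the transporter-family gene SLC16A14 (1.29 ± 0.19, adjusted p = 0.0128), the amino acid transporter SLC43A2 (1.06 ± 0.18, adjusted p = 0.0274) and EDC3 (chromosome 15, 74630558 to 74696292), an enhancer of mRNA decapping, which went from 49.1 ± 5.71 to 84.6 ± 5.84 CPM (0.78 ± 0.09, adjusted p = 0.00125). ANKRD13C, CDK6 and CEMIP made up the rest of the genes called higher, at 0.66 (adjusted p = 0.00125), 0.60 (0.0153) and 0.54 (0.0153), and are named here because their values had been seen. The ribosome biogenesis factor URB2 was the gene that fell, by 0.44 ± 0.08 on the log2 scale (adjusted p = 0.0471). XPO1, the export receptor that RanBP3 assists, stood at 1150 against 956 CPM (0.27 ± 0.08, adjusted p = 0.551) and RAN at -0.06. The AhR targets AHRR (0.40, adjusted p = 0.301) and TIPARP (0.22, adjusted p = 0.863) did not pass the test. Neither did the Wnt targets AXIN2 (-0.01) and LGR5 (0.50), the TGF-beta target SMAD7 (0.02), CDKN1A (-0.40), MYC (-0.10), FOS (0.18) or EGR1 (0.14).

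In all, 13 genes were called higher and 1 lower among 19607 tested, and 8 of the higher ones changed at least 2-fold. With an unadjusted p under 0.05 there were 614 higher and 571 lower genes, against 980 in all by chance. DESeq2 called 44 higher and 12 lower and limma-voom 13 and 0. With the replicate number as a block the counts were 26 and 4, and 1697 genes had an unadjusted p under 0.05. Without untreated replicate 2, the library at 46.7 CPM, the log2 fold change of CYP1A1 was 4.52 (adjusted p = 0.00725). DESeq2 gave CYP1A1 no p in any comparison, and without the cutoff for outlying counts its adjusted p was 0.00595. CYP1A1 lost its call without auxin replicate 1 (adjusted p = 0.077), 2 (0.065) or 3 (0.0542) and without untreated replicate 1 (0.104) or 3 (0.0799), and TXNIP without auxin replicate 1 (0.102), 2 (0.0635) or 3 (0.136) and untreated replicate 1 (0.115) or 2 (0.241). CYP1B1 lost it without auxin replicate 2 (0.0556), untreated replicate 1 (0.053) or 3 (0.0506), ADGRF1 without auxin replicate 1 (0.0628) or 2 (0.065) and untreated replicate 1 (0.0502) or 3 (0.0506). SLC16A14 lost it without each library other than auxin replicate 3 (0.0503 to 0.0813). SLC43A2 (0.065 to 0.266) and URB2 (0.0967 to 0.314) lost theirs whichever of the 6 libraries was left out. URB2 also lost it under other scaling (0.0568 to 0.0874), with limma-voom (0.0803), in the 6 libraries alone (0.054) and after thinning (0.129), and AHRR was called with DESeq2 (0.0496). CDK6 lost its call without auxin replicate 1 (0.102) or 2 (0.131) or any untreated replicate (0.0619 to 0.127), and CEMIP without each library other than untreated replicate 2 (0.0635 to 0.136). ARRDC3, ARRDC4, CCNG2, EDC3 and ANKRD13C kept theirs in every such fit. Exons of other genes overlap 13.02% of CYP1B1 and 13.74% of EDC3. The count of genes called higher fell to 6 without auxin replicate 1, to 5 without auxin replicate 2, to 7 without untreated replicate 1 and to 6 without untreated replicate 3.

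**Figure D2:**
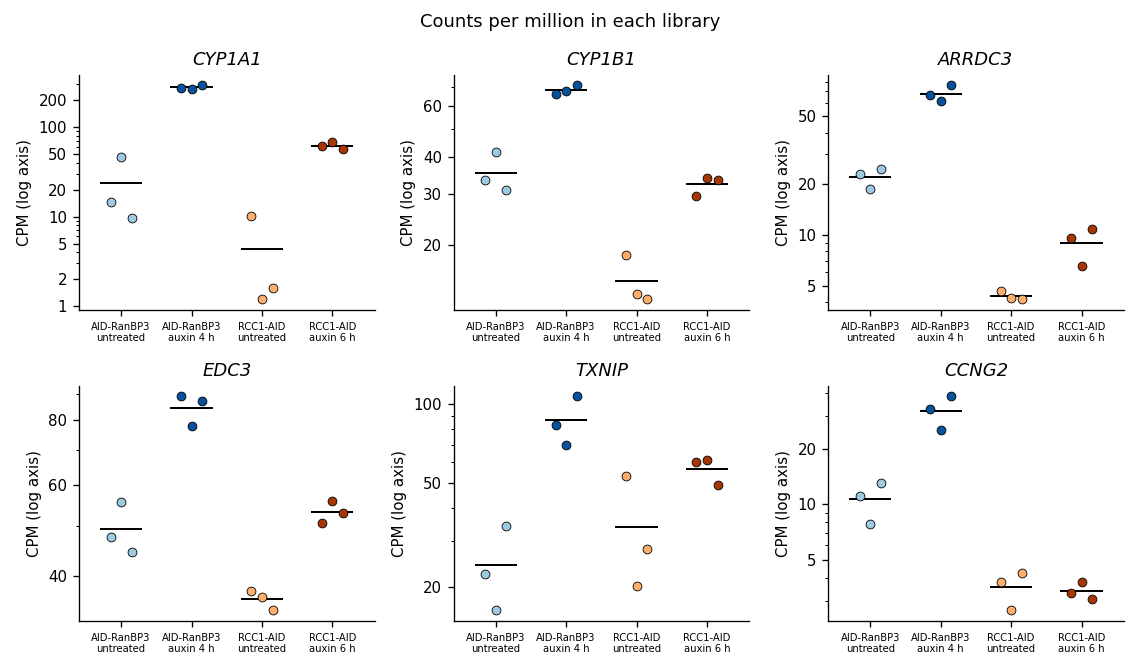
CPM (log axis) of CYP1A1, CYP1B1, ARRDC3, EDC3, TXNIP and CCNG2 in each library, by group on the horizontal axis. Points are single libraries and lines are means of 3; CYP1A1 lay at 266 to 291 CPM in auxin-treated AID-RanBP3 cells and at 9.52 to 46.7 CPM in untreated ones.

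Among the gene lists, AhR targets rose as a group in AID-RanBP3 cells. Of 8 tested members 7 had a positive log2 fold change, 2 (CYP1A1 and CYP1B1) were called over all genes and 3 were called adjusted over the list alone, with AHRR added (camera adjusted p = 1.04e-11, and 0.0185 with an estimated correlation). FOXO targets, genes induced when insulin and growth factor signalling is low, were positive in 17 of 19 members, with a median of 0.22. CCNG2 and TXNIP were called over all genes, and adjusted over the list alone 5 were called higher, with RICTOR (0.43), the repressor BCL6 (0.52) and YPEL2 (0.94) added. Their adjusted p was 1.34e-12 at the preset correlation and 0.138 with an estimated correlation.

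Replication-dependent histones were negative in 50 of 53 members (median -0.15, adjusted p = 6.84e-11; adjusted p = 0.667 with an estimated correlation), with H4C8 at -0.39 and H1-3 at -0.29. edgeR called 0 of them over all genes and adjusted over the list alone, DESeq2 and limma-voom also 0, and 1 higher and 10 lower had an unadjusted p under 0.05. Of the 9 abundant noncoding RNAs that serve as a sign of RNA quality 6 were negative beside them (median -0.06, adjusted p = 0.187). Ribosome biogenesis genes were negative in 37 of 40 members (median -0.10, adjusted p = 2.12e-09; adjusted p = 0.573 with an estimated correlation), and 4 were called lower adjusted over the list alone, URB2, NIP7 (-0.28), RRS1 (-0.29) and POLR1B (-0.24). G1/S genes of the E2F group were negative in 28 of 36 members (median -0.11, adjusted p = 1.26e-05; adjusted p = 0.573 with an estimated correlation), with CDC25A at -0.31 and DTL at -0.29. Zinc finger (ZNF) genes were positive in 242 of 389 members (median 0.05, adjusted p = 0.00816; adjusted p = 0.577 with an estimated correlation), and ZNF44 (0.70) was called adjusted over the list alone. Over all genes edgeR and limma-voom called 0 G1/S and 0 ZNF genes and DESeq2 0 and 2, with 6 lower G1/S genes and 38 higher and 10 lower ZNF genes at an unadjusted p under 0.05.

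No other list passed at the preset correlation in AID-RanBP3 cells. Adjusted p was 0.239 for Wnt/beta-catenin targets, 0.687 for TGF-beta, 0.525 for BMP targets, 0.728 for immediate early genes, 0.332 for ERK feedback genes, 0.949 for NF-kB, 0.508 for p53 targets, 0.695 for ATF4 targets, 0.352 for the ER unfolded protein response, 0.508 for heat shock genes, 0.213 for cholesterol synthesis and 0.246 for G2/M genes. It was 0.695 for ribosomal proteins, 0.518 for the Ran system and karyopherins, 0.208 for nucleoporins, 0.836 for hypoxia targets, 0.878 for YAP, 0.878 for NRF2 targets, 0.121 for interferon-stimulated genes, 0.0792 for clock genes, 0.208 for snoRNA host genes and 0.577 for CLK kinases and splicing regulators. Intestinal, fibroblast, leukocyte and endothelial markers gave 0.974, 0.767, 0.687 and 0.687. Adjusted over the list alone, single members of these lists were called, DUSP2 (-0.64), AEN (-0.49), PFKFB3 (-0.39) and NR1D2 (0.43).

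Treatment of RCC1-AID cells asked which transcripts change when the exchange factor of Ran is lost. After 6 h of auxin, RCC1-AID cells had CYP1A1 at 61.9 ± 5.84 CPM against 4.30 ± 5.05 CPM in untreated cells (3.87 ± 0.59, adjusted p = 0.0138), with untreated values of 10.1, 1.19 and 1.58 CPM. The log2 fold change was 5.50 without untreated replicate 1 and 4.56 with limma-voom, and DESeq2 without its cutoff for outlying counts gave an adjusted p of 0.0035. CYP1B1 rose from 15.0 ± 2.99 to 32.3 ± 2.47 CPM (1.11 ± 0.13, adjusted p = 0.00245), and its antisense transcript CYP1B1-AS1 by 1.27 ± 0.18 (adjusted p = 0.0114). Exons of other genes overlap 14.14% of CYP1B1-AS1, and reads in such overlaps cannot be told apart without the strand setting. JUN (chromosome 1, 58780788 to 58784327), a subunit of the AP-1 transcription factor, rose from 8.18 ± 4.31 to 24.6 ± 8.26 CPM (1.58 ± 0.28, adjusted p = 0.0481). ADGRF1 (1.15 ± 0.18, adjusted p = 0.016), ARRDC3 (1.04 ± 0.16, adjusted p = 0.0166) and EDC3 (0.56 ± 0.09, adjusted p = 0.0174) rose as well. ALDH1A3, a retinaldehyde dehydrogenase with 28.55% exonic overlap with other genes, rose by 0.87 ± 0.12 (adjusted p = 0.0114) and LEKR1 by 1.33 ± 0.19 (adjusted p = 0.0119). The pseudogene IGFL1P1 fell by 1.63 ± 0.21 on the log2 scale (adjusted p = 0.00744).

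RCC1-AID cells had no call for TXNIP (0.75 ± 0.28, adjusted p = 0.999) or CCNG2 (-0.06 ± 0.22). The remaining fixed genes did not pass either, with AHRR at 0.39 (adjusted p = 0.429), TIPARP at 0.21, FOS at 0.54 (adjusted p = 0.473), EGR1 at 0.45, MYC at 0.07, XPO1 at 0.13, RAN at 0.00, RANBP3 at -0.04, AXIN2 at -0.13, LGR5 at 0.51, SMAD7 at 0.13 and CDKN1A at 0.01. In all, 15 genes were called higher and 1 lower, 13 and 1 of them at least 2-fold, and 488 higher and 247 lower had an unadjusted p under 0.05. These are 735 in all, against 980 by chance, and 1271 with the replicate number as a block. A count below 980 in the main fit does not show that no genes changed. The block count does not show hidden changes either. Same-numbered RCC1-AID libraries did not all deviate together, and the block fit takes its spread from both lines. DESeq2 called 19 higher and 1 lower and limma-voom 18 and 1. Of the genes called higher, 6 lay below the expression minimum of the naming rule or had no symbol. HLA-DOA was among them, with 12, 16 and 22 counts with auxin and 0, 1 and 0 without (adjusted p = 0.0119), and is named because its values had been seen. So was the processed pseudogene H3C9P, at 3.44 against 0.259 CPM (3.73 ± 0.41), named for the same reason. Its adjusted p, 0.00203, was the smallest of this comparison. HLA-DOA lost its call with DESeq2 (0.0598), without auxin replicate 3 (0.0601) and without each untreated replicate (0.0562 to 0.109).

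Several of these calls were lost in other fits. In the 6 RCC1-AID libraries alone, CYP1A1 (adjusted p = 0.111), JUN (0.514), ADGRF1 (0.111), ARRDC3 (0.219), EDC3 (0.111) and LEKR1 (0.102) were not called. JUN also lost its call under upper quartile factors (0.0711), with at least 50 mean counts (0.126) and after thinning (0.173), as did ARRDC3 with limma-voom (0.0701). Thinning ended the calls of LEKR1 (0.16), ALDH1A3 (0.0965) and IGFL1P1 (0.969). The count of genes called higher fell to 3 without auxin replicate 3, 6 without untreated replicate 2 and 3 without untreated replicate 3. CYP1A1 lost its call without untreated replicate 2 (adjusted p = 0.0559) or 3 (0.12), and CYP1B1 kept its call in every alternative fit. JUN lost its call without auxin replicate 2 (0.0788) or 3 (0.232) and untreated replicate 1 (0.216) or 3 (0.412), and EDC3 without auxin replicate 2 (0.0861) or 3 (0.0975) and untreated replicate 1 (0.0562), 2 (0.108) or 3 (0.199). ADGRF1 lost it without auxin replicate 1 (0.0904) or 3 (0.0655) and untreated replicate 2 (0.101) or 3 (0.12), and ARRDC3 without auxin replicate 1 (0.0904) or 3 (0.111) and untreated replicate 2 (0.108) or 3 (0.143). Without auxin replicate 3 the adjusted p was 0.0655 for LEKR1, 0.0576 for CYP1B1-AS1 and 0.0549 for ALDH1A3, and without untreated replicate 3 it was 0.109 for each of them and 0.0565 for IGFL1P1.

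AhR targets rose as a group in RCC1-AID cells too. All 8 tested members had a positive log2 fold change (median 0.35, camera adjusted p = 1.23e-20, and 0.00491 with an estimated correlation), 2 were called over all genes, and adjusted over the list alone 4 were, CYP1A1, CYP1B1, AHRR and UGT1A6 (0.67). Immediate early genes were positive in 27 of 31 members (median 0.14, adjusted p = 4.79e-10; adjusted p = 0.323 with an estimated correlation), and adjusted over the list alone JUN, FOSB (1.17), FOS and EGR1 were called. All 39 G2/M genes were positive (median 0.17, adjusted p = 2.03e-16; adjusted p = 0.323 with an estimated correlation), with PLK1 at 0.24, CCNA2 at 0.27 and AURKA at 0.31; edgeR, DESeq2 and limma-voom called 0 of them, and 13 had an unadjusted p under 0.05. Histones were negative in 50 of 53 members (median -0.18, adjusted p = 1.8e-17; adjusted p = 0.323 with an estimated correlation), with H4C16 at -0.39 and H1-4 at -0.20; edgeR, DESeq2 and limma-voom called 0, and 1 higher and 11 lower had an unadjusted p under 0.05. Of the 9 abundant noncoding RNAs fixed as a sign of RNA quality 7 were negative beside them (median -0.13, adjusted p = 0.0236, and 0.521 with an estimated correlation). None of these RNAs had an unadjusted p under 0.05.

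Cholesterol synthesis genes were negative in 23 of 25 members (median -0.14, adjusted p = 8.84e-06; adjusted p = 0.521 with an estimated correlation), with SQLE at -0.28, and their adjusted p was 0.156 without untreated replicate 3. Hypoxia targets were negative in 18 of 24 members (median -0.16, adjusted p = 0.00152; adjusted p = 0.323 with an estimated correlation; 0.0581 without untreated replicate 3), with PFKFB4 at -0.49 and NDRG1 at -0.57. Wnt targets were negative in 15 of 20 members (adjusted p = 0.00399; adjusted p = 0.323 with an estimated correlation; 0.183 without auxin replicate 1), with NKD1 at -0.28. Ribosomal proteins were negative in 73 of 78 members (median -0.04, adjusted p = 0.00148; adjusted p = 0.727 with an estimated correlation), and the call was lost without auxin replicate 3 (0.707) or untreated replicate 1 (0.603) or 3 (0.0739). G1/S genes were negative in 28 of 36 members (median -0.05, adjusted p = 0.00566; adjusted p = 0.521 with an estimated correlation), and the call was lost without auxin replicate 2 (0.121) or untreated replicate 1 (0.0736) or 2 (0.0989). Over all genes and adjusted over the list alone, edgeR called 0 members of these lists, as did DESeq2 and limma-voom over all genes; at an unadjusted p under 0.05, cholesterol genes had 0, hypoxia targets 4 lower, Wnt targets 1 higher and 2 lower, ribosomal proteins 1 lower and G1/S genes 3 lower.

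Smaller shifts passed at the preset correlation for clock genes (11 of 15 positive, adjusted p = 0.0209; adjusted p = 0.381 with an estimated correlation), the abundant noncoding RNAs given above and CLK kinases and splicing regulators (15 of 25 negative, adjusted p = 0.0318; adjusted p = 0.72 with an estimated correlation). In these lists edgeR, DESeq2 and limma-voom called 0 members, edgeR also 0 adjusted over the list alone, with 3 higher clock genes, 0 noncoding RNAs and 3 lower splicing genes at an unadjusted p under 0.05. Clock genes lost the call without auxin replicate 3 (0.162) or untreated replicate 1 (0.351), the noncoding RNAs without auxin replicate 1 (0.549) or untreated replicate 2 (0.101) or 3 (0.156), and the splicing list without auxin replicate 2 (0.691) or 3 (0.179) or untreated replicate 1 (0.351) or 2 (0.0956). FOXO targets did not pass, with 7 positive and 12 negative members (median -0.06, adjusted p = 0.548), but did without untreated replicate 2 (0.0298). Adjusted p for the other lists was 0.345 for TGF-beta, 0.148 for BMP, 0.115 for ERK feedback, 0.403 for NF-kB, 0.18 for p53, 0.722 for ATF4, 0.722 for the ER response, 0.304 for heat shock, 0.315 for ribosome biogenesis, 0.682 for the Ran system, 0.933 for nucleoporins, 0.0576 for YAP, 0.304 for NRF2, 0.548 for interferon-stimulated, 0.0859 for snoRNA host and 0.603 for ZNF genes. Intestinal, fibroblast, leukocyte and endothelial markers gave 0.622, 0.722, 0.0859 and 0.548, and PECAM1 (1.18) was called adjusted over the endothelial list alone.

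**Figure D3:**
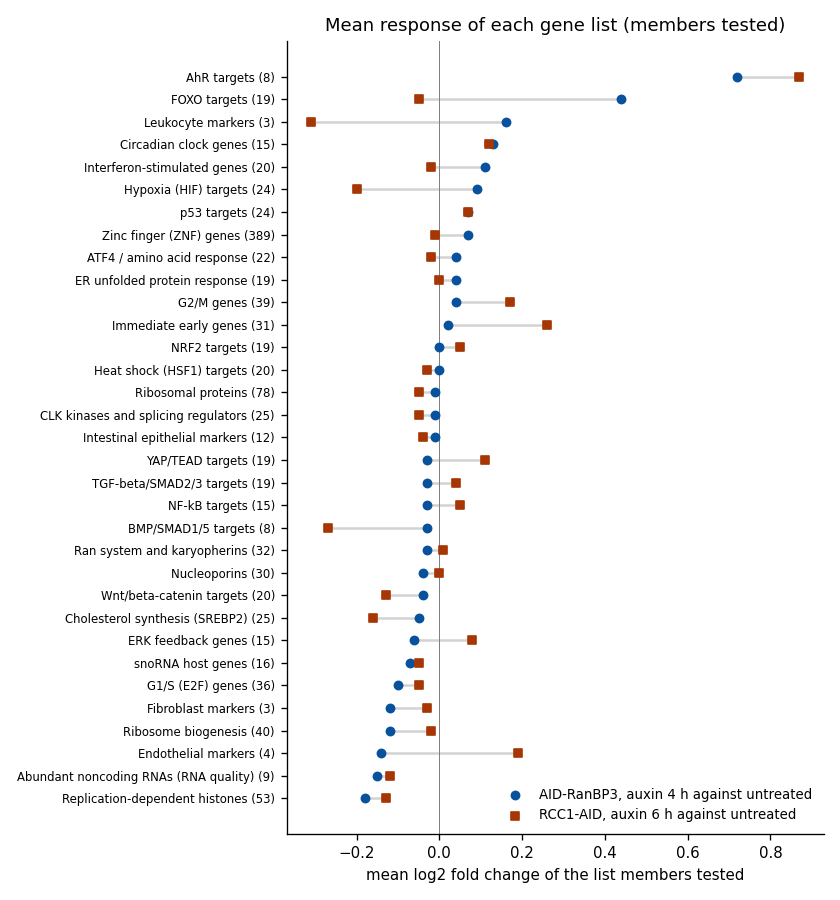
Mean log2 fold change with auxin over the tested members of each gene list (number of members in brackets) in AID-RanBP3 cells (circles, 4 h) and RCC1-AID cells (squares, 6 h), with grey lines joining the lines' values. AhR targets lie at 0.72 and 0.87; FOXO targets lie at 0.44 and -0.05.

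The auxin responses of the lines shared 5 risen genes, CYP1A1, CYP1B1, ARRDC3, ADGRF1 and EDC3. Independent lists would share 0.00995 genes (one-sided Fisher's exact p = 1.6e-13). With 1 fallen gene called in each line, none was shared (one-sided Fisher's exact p = 1). The test takes genes and lists as independent. But both lists came from 1 model with a shared estimate of spread, and CYP1A1 and EDC3 lie 23.2 kb apart. With each line's 6 libraries fitted alone, 1 gene was shared, CYP1B1. The shared count fell to 3, 2, 2 and 2 without AID-RanBP3 auxin replicate 1 or 2 or untreated replicate 1 or 3, to 3 and 2 without RCC1-AID auxin replicate 1 or 3, and to 1, CYP1B1, without RCC1-AID untreated replicate 2 or 3. Of the genes called in AID-RanBP3 cells 13 of 14 moved the same way in RCC1-AID cells, and of those called in RCC1-AID cells 13 of 16 moved the same way in AID-RanBP3 cells. Across all 19607 genes the log2 fold changes correlated weakly (r = 0.0532, rho = 0.138, 56.7% with the same sign), and the sign of r turned without AID-RanBP3 auxin replicate 1 (-0.00712), RCC1-AID auxin replicate 1 (-0.00289) or RCC1-AID untreated replicate 2 (-0.0284). Across the 14486 genes with a mean log2 CPM of at least 1, r was 0.252 and rho 0.241. Genes are not independent replicates, so these are descriptions.

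**Figure D4:**
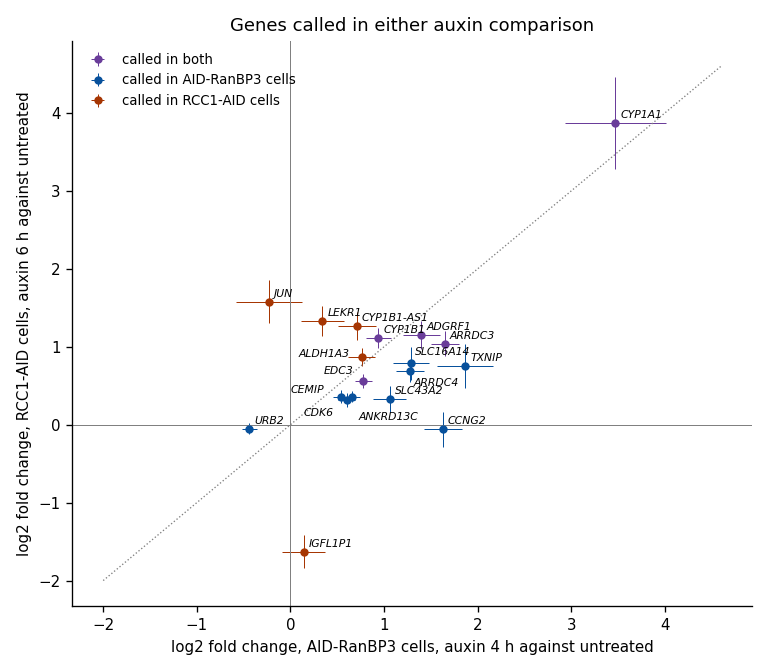
Log2 fold change with auxin in AID-RanBP3 cells (horizontal axis, 4 h) and RCC1-AID cells (vertical axis, 6 h) for genes called in either comparison with a symbol and a mean log2 CPM of at least 1. Bars are SE and the dotted line marks equal responses; CCNG2 lies at 1.63 and -0.06 and JUN has its rise in RCC1-AID cells.

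The difference between the responses was tested directly, with the line and the time of treatment differing along with the protein. The response in RCC1-AID cells minus that in AID-RanBP3 cells was -1.70 ± 0.29 for CCNG2 (adjusted p = 0.206), -1.77 ± 0.32 for IGFL1P1 (adjusted p = 0.206) and -0.95 ± 0.18 for BCL6 (adjusted p = 0.317), and none of these passed. JUN stood at 1.81 ± 0.44 (adjusted p = 1), TXNIP at -1.12 ± 0.41 (adjusted p = 1), CYP1A1 at 0.39 ± 0.76 and CYP1B1 at 0.17 ± 0.18. edgeR called 0 genes, with 377 higher and 281 lower at an unadjusted p under 0.05. That makes 658 in all, against 980 by chance, and 933 with the replicate number as a block. limma-voom called 0, and DESeq2 called LINC02939 and TRIM16 higher and BCL6, CCNG2, IGFL1P1 and NEDD9 lower, named because their values had been seen. With the replicate number as a block CCNG2 and SLC38A2 were called lower, and without RCC1-AID untreated replicate 2 JUN was called higher. By exact enumeration the rise of the AhR list mean, 0.79 in AID-RanBP3 and 0.94 in RCC1-AID cells, differed by 0.15 (p = 0.79), and camera gave an adjusted p of 0.318 for the difference.

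Untreated RCC1-AID and AID-RanBP3 cells differed in 8305 genes, 42.4% of those tested, with 4005 higher and 4300 lower in RCC1-AID cells and 558 and 923 of them at least 2-fold. ZNF714, a zinc finger gene, stood at 14.5 against 0.0777 CPM (7.49 ± 0.27, adjusted p = 6.56e-11), and PODXL2 (4.46 ± 0.17), SRPX (3.65), SYNE3 (2.87) and the small RNA SNORA54 (2.85) followed. ZNF708 was lower, at -6.08 ± 0.34 (adjusted p = 3.45e-09). It was -7.52 without RCC1-AID untreated replicate 2. MIR1244-2, SNORD97, RNU5E-6P and RNU5B-1, the other genes with the largest falls, share sequence or exons with other genes and are uncertain. The export receptor XPO1 was lower, at 341 ± 11.8 against 956 ± 60.7 CPM (-1.49 ± 0.08, adjusted p = 3.12e-09), as was the Ran regulator RANBP1 (-1.96 ± 0.08, adjusted p = 1.84e-10). CYP1A1 was lower in untreated RCC1-AID cells (-2.56 ± 0.59, adjusted p = 0.00245; -1.53 with adjusted p = 0.053 without AID-RanBP3 untreated replicate 2, and -4.19 without RCC1-AID untreated replicate 1), and so was CYP1B1 (-1.25, adjusted p = 2.51e-06). RANBP3 was higher (0.43, adjusted p = 0.000564) and RCC1 was not called (0.00, adjusted p = 0.983). With offsets for GC content and gene length 6331 genes were called, 4414 of the 8305 were still called in the same direction, and XPO1 stood at -0.98.

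By list, histones were higher in untreated RCC1-AID cells, with 38 of 53 members called over all genes and 41 adjusted over the list alone, all higher (median 0.50), for example H2BC13 (1.21), H2BC21 (1.34) and H1-2 (0.56). Their adjusted p was 3.94e-10 at the preset correlation and 0.943 with an estimated correlation. The list of abundant noncoding RNAs fixed as a sign of RNA quality moved the same way, with 6 members called higher and 1 lower of 9 (median 0.57, adjusted p = 0.118), SCARNA2 at 1.31 and MALAT1 at -1.89. A group of small structural RNAs took 6.26% to 7.13% of counts in AID-RanBP3 and 7.21% to 10.8% in RCC1-AID libraries. These shares are too high in both lines, since RN7SL1 and RN7SK each entered under more than 1 ID with identical counts. Ran system and karyopherin genes went both ways, with 7 called higher and 14 lower, over all genes and adjusted over the list alone, and importins among the lower ones, IPO11 at -1.08, KPNA3 at -0.92 and IPO7 at -0.75 (adjusted p = 0.0111; adjusted p = 0.943 with an estimated correlation). CLK kinases and splicing regulators were lower in 14 of 25 members and higher in 1, the same counts as adjusted over the list alone (adjusted p = 0.0111; adjusted p = 0.943 with an estimated correlation), with SRSF6 at -0.70 and LUC7L3 at -0.99. Ribosomal proteins were called higher in 32 and lower in 8 of 78, and likewise adjusted over the list alone (adjusted p = 0.0113; adjusted p = 0.943 with an estimated correlation), and this list lost its call without AID-RanBP3 untreated replicate 2 (0.227) or RCC1-AID untreated replicate 1 (0.0922).

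The other lists did not pass between the untreated lines even though many members were called over all genes. Counts of members called higher and lower were 6 and 3 for Wnt targets, 8 and 3 for TGF-beta, 1 and 0 for BMP, 5 and 4 for immediate early genes, 5 and 3 for ERK feedback, 4 and 1 for NF-kB, 6 and 8 for p53, 4 and 2 for ATF4, 4 and 7 for the ER response, 3 and 5 for heat shock, 4 and 9 for cholesterol synthesis, 15 and 9 for G1/S, 10 and 16 for G2/M and 11 and 11 for ribosome biogenesis genes. They were 8 and 7 for nucleoporins, 6 and 5 for hypoxia, 3 and 2 for YAP, 4 and 5 for NRF2, 5 and 2 for interferon-stimulated, 5 and 2 for clock, 7 and 3 for snoRNA host and 44 and 112 for ZNF genes. AhR targets counted 1 and 2 and FOXO targets 1 and 6. Marker lists counted 1 and 4 for intestinal, 1 and 0 for fibroblast, 1 and 0 for leukocyte and 0 and 1 for endothelial genes, with COL1A1 at 1.56 and CD68 at 0.84. Adjusted over the list alone, the counts differed from these by at most 2. Camera adjusted p for these lists was between 0.134 and 0.979.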

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

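The tests of auxin exposure itself, of a preparation batch and of FOXO responses acting alike in both lines, with its form within pairs, were chosen only after the results were seen.

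A set of 5 genes, CYP1A1, CYP1B1, ARRDC3, ADGRF1 and EDC3, was higher with auxin in both lines. After thinning every library to 9326243 counts each gene kept at least 0.823 of its log2 fold change in both lines. Random thinning leaves the expected fold change as it is, so this cannot decide whether library depth played a part. In the thinned RCC1-AID libraries ARRDC3 (1.04 ± 0.16 before, 0.91 ± 0.22 after, adjusted p = 0.525), EDC3 (0.56 ± 0.09 before, 0.46 ± 0.11 after, adjusted p = 0.525) and ADGRF1 (1.15 ± 0.18 before, 1.12 ± 0.20 after, adjusted p = 0.0965) lost their calls. By exact enumeration no difference between lines was found in the rise of the AhR list (two-sided p = 0.79). With 3 libraries per group this does not show that the rises were equal. Of the 5 genes the list holds only CYP1A1 and CYP1B1, so the test does not cover ARRDC3, ADGRF1 and EDC3. Auxin exposure itself remains a hypothesis. It cannot be told apart from a shared effect of losing either protein, because no cells without a degron tag were treated here. What acts on the 5 genes stays open.

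The untreated lines differed in 8305 genes. After offsets for GC content and gene length a share of 0.531 was still called in the same direction (0.481 to 0.529 with 1 untreated library left out), and 6331 genes were called in all. This bias may thus underlie part of the difference and cannot be told apart from it. The tables argue against reads shared with other genes for the called genes as a whole. Of these, 26.4% share at least 10% of their 50-base stretches with another gene, against 28.8% of all tested genes. The genes at least 2-fold lower do so 1.15 times as often as all tested genes, at 33.1%, against 23.6% of those at least 2-fold higher. Of 656 processed pseudogenes 109 were at least 2-fold lower and 22 at least 2-fold higher. Shared reads therefore stay open for the large falls. A separate preparation or processing batch cannot be told apart from the line, since a 5.8S rRNA gene had at most 26 counts in the RCC1-AID libraries and 429 to 614 in the AID-RanBP3 libraries. A difference between the clones themselves was not tested and stays open.

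FOXO targets had higher values with auxin in AID-RanBP3 cells (adjusted p = 1.34e-12, and 0.138 with an estimated correlation) than in RCC1-AID cells, a difference between groups (camera adjusted p = 1.07e-10 for the difference of responses, median -0.34, and 0.413 with an estimated correlation). The median kept 1.12 of its value in thinned libraries, but random thinning leaves the expected fold change as it is, so this cannot decide on depth. The tables argue against 1 uneven library, as the lowest median with a library left out was 0.784 of its value. The rise of the list mean, 0.44 against -0.04, gave an exact two-sided p of 0.06 over splits that ignore the pairs (adjusted p = 0.66 over the lists). The exact p was 0.0875 when AID-RanBP3 libraries were exchanged only within pairs, which rose by 0.38, 0.43 and 0.5. Auxin acting alike at 4 and 6 h thus cannot be told apart from a response of AID-RanBP3 cells. CCNG2, the member that differed most, was also lower in untreated RCC1-AID cells (-1.55).

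For the difference of responses, camera at the preset correlation also passed other lists. G2/M genes gave an adjusted p of 7.9e-06 (median 0.12, 0.824 with an estimated correlation; 0.0985 without AID-RanBP3 untreated replicate 1 and 0.248 without RCC1-AID auxin replicate 1). Ribosome biogenesis genes gave 0.000148 (median 0.08, 0.824 with an estimated correlation; 0.12 without AID-RanBP3 auxin replicate 3). Immediate early genes gave 0.000291 (median 0.17, 0.824 with an estimated correlation; 0.051 without RCC1-AID auxin replicate 3 and 0.106 without RCC1-AID untreated replicate 1), with JUN, DUSP2 and FOSL1 called higher adjusted over the list alone. ZNF genes gave 0.00767 (median -0.05, 0.692 with an estimated correlation; 0.119 without RCC1-AID auxin replicate 2). Hypoxia targets gave 0.0132 (median -0.14, 0.692 with an estimated correlation; 0.151 and 0.139 without AID-RanBP3 auxin replicate 3 or untreated replicate 2, and 0.155 without RCC1-AID untreated replicate 3). ERK feedback genes gave 0.0361 (median 0.06, 0.851 with an estimated correlation; 0.0511 and 0.237 without AID-RanBP3 auxin replicate 1 or 3, 0.165 without AID-RanBP3 untreated replicate 2, and 0.543 and 0.735 without RCC1-AID auxin replicate 3 or untreated replicate 1). By exact enumeration of list means, p was 0.39 for G2/M, 0.235 for ribosome biogenesis, 0.3 for immediate early, 0.025 for ZNF (adjusted p = 0.413 over the lists), 0.21 for hypoxia and 0.43 for ERK feedback genes, so a difference in these lists rests on the preset correlation. edgeR, DESeq2 and limma-voom called 0 of their members over all genes, and at an unadjusted p under 0.05 the higher and lower members numbered 5 and 0, 2 and 0, 5 and 0, 4 and 21, 1 and 2, and 2 and 0, in that order.

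The 10 splits of 6 libraries are too few for a share under 0.05. The real AID-RanBP3 split called 14 genes and the highest other 0, so 1 split called as many; among the 4 splits that part all 3 same-numbered pairs the highest other was also 0. The untreated lines gave 8305 and 0, again 1 split. The RCC1-AID split called 16 genes and the highest other 28, so 2 splits called as many. That other split, auxin replicates 1 and 2 with untreated replicate 1 against the rest, shared 0 genes with the real one and held 19 small noncoding genes. It keeps together auxin 1 with untreated 1 and auxin 3 with untreated 2, whose deviations correlated at 0.573 and 0.739. Splits that part such pairs were not examined separately in RCC1-AID cells. For the difference of responses the real count is 0, so all 100 splits drawn call at least as many whatever the data, and this count decides nothing (highest 159).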

How the results depend on the processing

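Thinning, the GC and length offsets, the use of 1 ID of each identical set and the mean auxin effect were chosen only after the results were seen. For single named genes, 1596 values over the alternatives kept their direction and side of the threshold, 99 lost the threshold, 9 gained it and 2 turned. The 2 were AHRR (-0.27) and SMAD7 (-0.03) between the untreated lines under GC and length offsets. For gene lists 501 values stayed, 111 lost and 8 gained the threshold. For counts, overlap and correlation 148 stayed, 58 moved and 4 turned. Causes were not tested, except that fits with fewer libraries or counts have less power by construction. Between the untreated lines the median log2 fold change of all genes was 0.0563 in the main fit, and line changes are read relative to it. It was 0.115 under upper quartile factors, with 4889 genes called higher and 3832 lower. The shift went the other way with RLE size factors (0.0324, 3703 higher and 4476 lower) and library totals (0.0266, 3587 higher and 4498 lower).

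Genes called higher in AID-RanBP3 cells with auxin numbered 72 with no filter, 44 with DESeq2, 22 with GC and length offsets, 8 with a 2-fold minimum, and 5 to 9 with 1 library left out. Genes called lower numbered 0 with RLE size factors, library totals, upper quartile factors, limma-voom, the 6 libraries alone, thinning and a 2-fold minimum, 43 with no filter, 12 with DESeq2, 3 with GC and length offsets (CDCA7, TRIM16 and URB2), and 0 to 1 with 1 library left out. In RCC1-AID cells the higher genes numbered 79 with no filter, 8 with at least 50 mean counts, 5 in the 6 libraries alone, 4 after thinning, and 3 to 12 with 1 library left out. The lower ones numbered 16 with no filter, 0 after thinning, and 0 to 1 with 1 library left out. Between the untreated lines a 2-fold minimum left 558 higher and 923 lower genes, and leaving out 1 library gave 3034 to 3858 higher and 3683 to 4228 lower. For the difference of responses no filter called 16 higher and 23 lower, DESeq2 2 and 4, and leaving out 1 library 0 to 1 higher and 0 lower. Genes shared by both responses numbered 12 with no filter, 1 in the 6 libraries alone (CYP1B1), 2 after thinning (CYP1A1 and CYP1B1), and 1 to 5 with 1 library left out. The correlation of the responses was -0.014 with no filter, 0.254 with at least 50 mean counts, 0.157 with each line's 6 libraries alone, 0.0938 after thinning, and -0.0284 to 0.0799 with 1 library left out, against an SD of 0.0336 over those fits.

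With the replicate number as a block, AID-RanBP3 calls were 26 higher and 4 lower, and the difference of responses had 2 lower. Same-numbered RCC1-AID libraries did not all deviate together (0.573, -0.151 and -0.156 for numbers 1, 2 and 3). Between the lines, same-numbered untreated libraries deviated together for numbers 2 (0.383) and 3 (0.32) but not for number 1 (-0.067). A link between the lines through the replicate number therefore stays open. As a hint from the data, RCC1-AID auxin libraries 1, 2 and 3 correlated best with untreated 1 (0.573), 3 (0.368) and 2 (0.739), so not each with its own number. The block counts were 20 and 1 in RCC1-AID cells and 4240 and 4396 between the lines. The block changed no list call. After thinning to 9326243 counts, genes called higher went from 15 to 4 in RCC1-AID and from 13 to 14 in AID-RanBP3 cells.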

Other observations

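The tests of the mean auxin effect, with its splits by pairs, of noncoding genes, of neighbouring genes and of read-through were chosen only after the results were seen.

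Averaged over both lines, auxin raised 28 genes and lowered 0 with edgeR, and 1264 had an unadjusted p under 0.05. Of the risen genes 11 were called in neither line alone. They included AHRR, the AhR repressor that AhR itself induces (0.39 ± 0.07, adjusted p = 0.0273), the efflux transporter ABCG2 (0.81 ± 0.14, adjusted p = 0.0273) and the interleukin 1 receptor antagonist IL1RN (0.74 ± 0.13, adjusted p = 0.0273), named because their values had been seen. Of the 100 splits drawn 6 called at least as many genes, and the highest other called 208, so chance is not excluded over splits that ignore the pairs. The real split parts all 3 same-numbered AID-RanBP3 pairs, and among the 38 drawn that do so the highest other called 0. The 5 others as large part 1 pair and called 62 to 208, for a reason that was not tested. In AID-RanBP3 cells alone the splits that part fewer pairs called 0 genes. The AhR list mean rose by 0.87, with the smallest exact p that 400 splits can give, 0.005 (adjusted p = 0.165 over the lists).

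Between the untreated lines 42.4% of all tested genes were called, and no test between gene classes was run. Processed pseudogenes were lower in RCC1-AID cells in 157 of 656 tested and higher in 38, with a median of -0.25, while snoRNA genes were higher in 84 and lower in 38 of 251, with a median of 0.41. In RCC1-AID cells with auxin, 68.7% of the 243 noncoding genes with an unadjusted p under 0.05 were higher, against 65.4% of the 488 protein-coding genes. The difference of 3.3 points had a 95% interval of -3.84 to 10.6, with genes taken as independent, which they are not, so whether noncoding transcripts rose further could not be decided. In AID-RanBP3 cells the shares were 37.6% of 263 noncoding and 55.9% of 919 protein-coding genes.

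CYP1A1 and EDC3 lie 23.2 kb apart on chromosome 15 and both rose. If the whole rise of EDC3 were transcription running on from CYP1A1 at a fixed share, its gains would scale with those of CYP1A1. But EDC3 gained 2.08 times as many CPM in AID-RanBP3 as in RCC1-AID cells (range 1.94 to 2.28 with 1 library left out) and CYP1A1 4.41 times (4.19 to 4.65). Read-through as part of the rise, or at a share that differs between the lines, was not tested. Neighbours within 100 kb of the shared genes also lay higher, with CYP1A1 and EDC3 taken as 1 locus. Leaving out neighbours that overlap or are called and each locus in turn, their mean of medians stood at least at the 96.6 percentile of 10000 random sets, so local effects may add to the rise, as a hypothesis. The mean of medians was 0.67 over 3 loci and 0.15 without CYP1B1, and 2 of the loci had a single such neighbour, ENSG00000280276 (1.72) at CYP1B1 and LUCAT1 (0.16) at ARRDC3.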
